A study of Danio rerio with 12 samples.

How the data were processed

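The series holds RNA-seq of zebrafish ventricles, 12 libraries in 4 groups of 3: uninjured and injured, each in tp53 wild-type and tp53 mutant fish. Per the labels' protocols, atrium and outflow tract were removed, 5 ventricles were pooled per sample, and total RNA was extracted with Trizol and sequenced as single-end reads of 50 bp. Per the same protocols, reads were trimmed with Trim Galore 0.6.4 at quality 15 and mapped with TopHat 2.1.1 to danRer10 with the UCSC RefSeq annotation. The deposited gene counts came from htseq-count, given as version 1.6.1 per the submitters' processing notes, over reads with a mapping quality above 30. The labels' protocols name DESeq2 for the authors' own testing, whose results are not used here.

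Those steps bear on the values. The strand setting of the counting is not given in the sources used here, so overlapping and antisense genes cannot be told apart. The mapping quality filter drops reads shared by near-identical genes, so hemoglobin, actin and ribosomal protein genes are uncertain. Reads of 50 bp make that loss larger for paralogs. The deposited files end in rows that name no gene, which took 36.7% to 38.9% of reads in injured and 40.8% to 44.9% in uninjured libraries, and these rows were left out of library sizes and tests. Counts in genes totalled 18146336 to 20528705 per library. At that depth a count of 0 allows up to 3 counts, or 0.146 to 0.165 CPM (counts-per-million) before TMM scaling. Intervals and such limits cover counting error only. Within each group the lowest chi-square per degree of freedom between 2 libraries was 10.5, so no library was a repeat of another.

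The counts were analysed in R 4.3.3. Genes with low counts were removed with filterByExpr of edgeR 4.0.16, which left 11344 of 14781 genes and removed 3437. Libraries were scaled by TMM. All 12 libraries entered 1 model with a mean per group and no covariate, fitted by glmQLFit with robust estimation, and each contrast was tested by edgeR's quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment at 0.05. The biological coefficient of variation was 0.24. Standard errors were derived from the fold change and F. The contrasts were injury in wild type, injury in mutants, genotype in uninjured ventricles, genotype in injured ventricles, genotype averaged over both, and the interaction. Principal components and gene values used TMM-normalized CPM, with a prior count of 2 on the log2 scale for the components.

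A set of 31 gene lists was fixed before the data were examined, from general knowledge of zebrafish gene symbols. Of 1304 entries, 1031 matched the files as written, 50 by an older symbol through the GRCz12tu gene table, 37 repeated a gene already in the list, and 186 were not matched. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation. The fry test, which asks whether the genes of a list move one way on balance, was run beside it. Named genes follow a rule fixed at the same time. It takes up to 8 genes with the highest and lowest fold changes per contrast, among those past the threshold with a mean of at least 5 CPM and, for 2-group contrasts, no overlap between groups. It adds the 4 members with the smallest adjusted p of each list that passed camera, tp53 with its 6 most abundant targets, and the 4 smallest interaction p-values. Genes outside the rule are said to be so. For neighbours of tp53, 14578 gene rows were matched to the GRCz12tu table, whose positions served only to tell which genes lie within 10 Mb. They are not printed because the files use another build.

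The pipeline was tested on simulated counts drawn from these libraries' means. For genotype in injured ventricles, edgeR recovered 65% of 100 genes changed by log2 1 and 93% of 100 changed by log2 2 among 11242 genes, with 15 false among 173 calls. DESeq2 1.42.0 recovered 86% and 99% with 53 false among 238 calls, over 11344 genes. Both shares of false calls exceeded the 0.05 threshold, that of DESeq2 by more, so its calls and adjusted p-values below are less certain. For the interaction, edgeR recovered 23% and 87%, with 7 false among 117 calls. The changed genes were drawn from those with a mean of at least 5 CPM, and all were changed at once. Many calls loosen the adjusted threshold, so recovery may be lower in the real genotype contrasts, where few genes passed. In camera, 5 of 200 unshifted lists had p under 0.05. The simulated genes were drawn independently of each other, so this says nothing about lists whose members move together. For genotype in injured ventricles, oxidative phosphorylation genes had an estimated correlation of 0.84. The alternatives were DESeq2, RLE size factors, TMM factors without the erythrocyte, sarcomere and oxidative phosphorylation lists, 2 other filters, a fit of the compared groups alone, the replicate number as a block, and leaving out each library in turn.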

Results

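RNA was measured by sequencing of ventricles from adult zebrafish, a species that rebuilds heart muscle after injury. The 12 libraries formed 4 groups of 3, which crossed injury with tp53 genotype. Each sample pooled 5 ventricles. In injured fish, tamoxifen switched on diphtheria toxin A in cardiomyocytes, the contracting cells of the heart, through a CreER recombinase driven by a cardiomyocyte promoter, and ventricles were taken 7 days later. Mutant fish carried tp53 M214K, a missense allele that impairs the DNA-binding p53 protein. All fish received 0.5 µM tamoxifen for about 17 hours. The genotypes given for uninjured fish lack the ablation transgenes, so injury and transgene carriage could not be separated. The title of the series places the comparisons in a study of tp53 and cardiomyocyte proliferation during heart regeneration.

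Gene counts totalled 18146336 to 20528705 per library, and 11344 of 14781 genes were tested. The 10 most abundant genes took 9.6% to 13.5% of the counts in injured and 21.2% to 23.8% in uninjured libraries. Nothing in the labels says whether the 3 samples of a group came from separate cohorts, so p-values measure the spread between these samples, which may be partly technical. The first principal component held 72.7% of the variance and separated injured from uninjured libraries. Uninjured wild-type replicate 2 lay at 16.2 on it, while the other 5 uninjured libraries lay between 52.4 and 81.4 and the injured libraries between -74.3 and -43.7. The files give no coordinates, so genes are named by symbol alone.

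**Figure D1:**
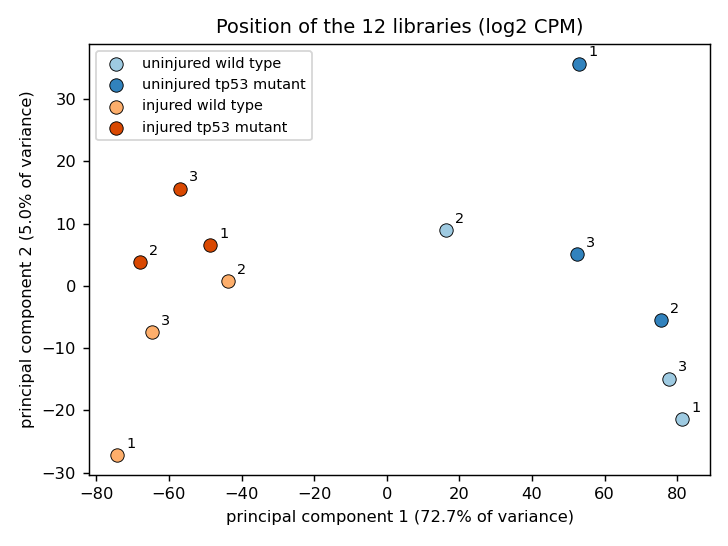
Principal components 1 (horizontal) and 2 (vertical) of log2 counts-per-million (CPM), 1 point per library, coloured by group and numbered by replicate. Injured libraries lie at or below -43.7 on component 1, and uninjured wild-type replicate 2 lies at 16.2, nearer to them than any other uninjured library.

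The tp53 transcript itself was present in every library, at 75 to 154 TMM-normalized counts-per-million (CPM). Means were 98.1 ± 14.8 CPM (SD, n = 3) in uninjured wild type, 85.9 ± 15.6 in uninjured mutants, 141 ± 12.2 in injured wild type and 99.2 ± 10.1 in injured mutants. The allele changes the protein and its RNA level need not change. The genotype contrast of tp53 missed the threshold in uninjured (log2 fold change -0.19, SE 0.16, edgeR adjusted p = 0.918) and injured ventricles (-0.50, SE 0.16, edgeR adjusted p = 0.379). The transcript of mdm2, a direct p53 target that encodes the ubiquitin ligase limiting p53, separated the genotypes in all libraries of each injury state. It reached 57 ± 7.67 CPM in uninjured wild type against 39.2 ± 1.76 in uninjured mutants, and 92.3 ± 9.63 in injured wild type against 18.1 ± 0.397 in injured mutants (SD, n = 3 each).

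**Figure D2:**
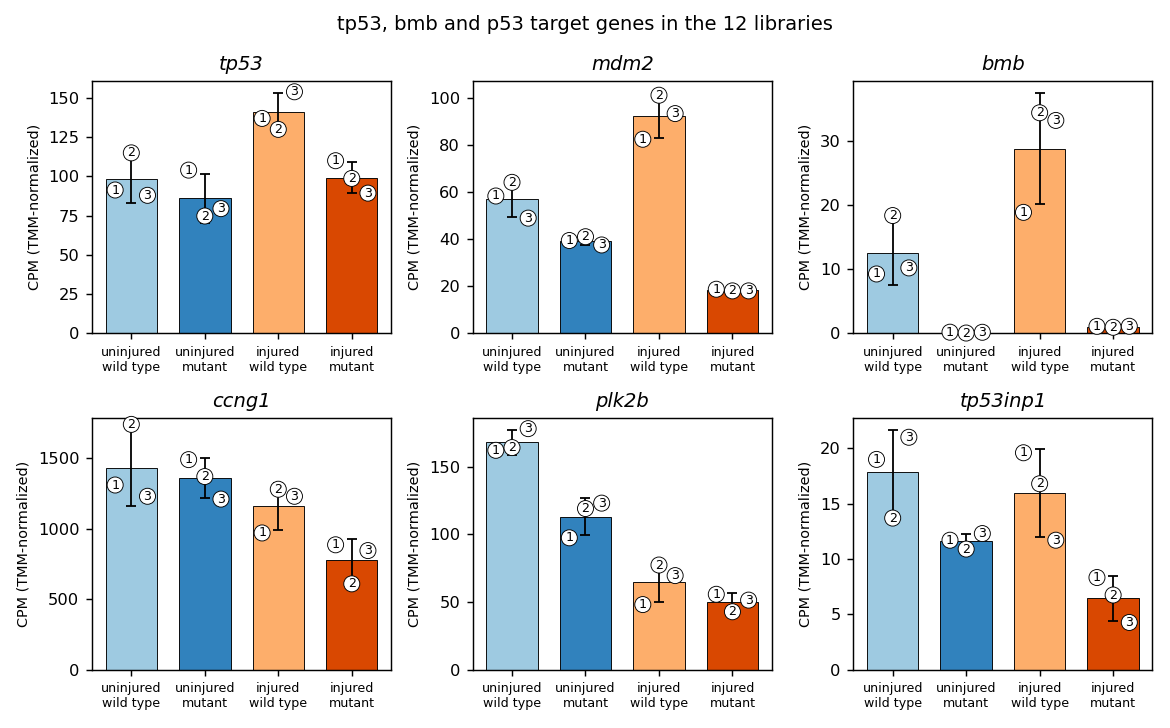
TMM-normalized CPM of 6 genes by group. Bars are means, error bars SD (n = 3), and numbered circles single libraries. The mdm2 mean was 92.3 in injured wild type and 18.1 in injured mutants, while the bmb means of the mutant groups were 1 and 0.0829.

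The first comparison asked what injury changed in wild-type ventricles. Cell division genes rose, genes of the extracellular matrix and of macrophages rose, and genes of mitochondrial energy metabolism and of the contractile apparatus fell. The mitotic genes anln and kif20a rose by log2 3.26 (SE 0.48) and 2.74 (SE 0.39), and rrm2, a ribonucleotide reductase subunit needed for DNA synthesis, by 3.04 (SE 0.36). In the opposite direction, the mitochondrial complex I gene ndufb7 fell by 2.2 (SE 0.18) and myl7, the atrial and ventricular myosin light chain gene of the zebrafish heart, fell by 2.25 (SE 0.28) on the log2 scale. In total 6269 genes passed edgeR's adjusted threshold of 0.05, 2920 higher and 3349 lower, and 3093 of them changed at least 2-fold. Which direction had more genes depended on the method, with 3213 higher and 3001 lower under RLE size factors and 3367 higher and 3091 lower by DESeq2.

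Of 44 tested G2/M and mitosis genes, 43 rose (43 adjusted over the list alone) and 1 did not pass, with a median log2 fold change of 2.67. Of 39 DNA replication and G1/S genes, 37 rose (37 adjusted over the list alone), among them dhfr (1.98, SE 0.18) and ccne1 (2.15, SE 0.30). Both lists passed camera with its preset correlation (adjusted p = 4.38e-18 and 5.83e-16). Neither passed when the correlation was estimated (adjusted p = 0.346 for each, with an estimated correlation). Of 45 fibroblast and extracellular matrix genes, 36 rose and 1 fell (37 and 1 adjusted over the list alone, camera adjusted p = 7.88e-12, adjusted p = 0.339 with an estimated correlation). The collagen gene col1a2 rose by 2.23 (SE 0.30), htra1a, a secreted protease, by 2.75 (SE 0.29), and lum, a collagen-binding proteoglycan, by 4.29 (SE 0.55).

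Macrophage, cytokine and lymphocyte markers were higher in the same libraries. Of 42 macrophage genes, 32 rose and none fell (35 and 0 adjusted over the list alone, camera adjusted p = 1.59e-08, adjusted p = 0.376 with an estimated correlation), including the cathepsin gene ctsba (2.25, SE 0.42). Of 33 inflammatory cytokine and complement genes, 20 rose and 1 fell (21 and 1 adjusted over the list alone, camera adjusted p = 0.00017, adjusted p = 0.339 with an estimated correlation). The chemokine gene ccl35.2 rose by 5.14 (SE 1.06). Of 27 lymphocyte genes, 12 rose and 1 fell (12 and 1 adjusted over the list alone, camera adjusted p = 0.00365, adjusted p = 0.339 with an estimated correlation), and foxp3a, a regulatory T cell factor, rose by 3.67 (SE 0.58). Neutrophil genes did not pass camera, with 2 higher and 3 lower of 15 (1 and 2 adjusted over the list alone, camera adjusted p = 0.543), nor did interferon genes, with 9 higher and 2 lower of 30 (9 and 1 adjusted over the list alone, camera adjusted p = 0.324).

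Genes of cardiomyocyte function moved down. Whole ventricles were sequenced after cardiomyocyte ablation. Here, as for the matrix and immune lists, a changed mix of cells cannot be told from changes within cells. Of 83 nuclear-encoded oxidative phosphorylation genes, 76 fell and 4 rose (76 and 4 adjusted over the list alone), with a median of -1.25 (camera adjusted p = 1.25e-20, adjusted p = 0.376 with an estimated correlation). Of 47 fatty acid oxidation and TCA cycle genes, 40 fell and 1 rose (40 and 1 adjusted over the list alone, camera adjusted p = 3.23e-16, adjusted p = 0.339 with an estimated correlation). The fatty acid carrier gene fabp3 fell by 2.33 (SE 0.18), and mdh2, a TCA cycle enzyme gene, by 2.40 (SE 0.23). Of 28 sarcomere genes, 19 fell and 2 rose (19 and 2 adjusted over the list alone, camera adjusted p = 3.04e-05, adjusted p = 0.376 with an estimated correlation). Here acta1a, an alpha-actin gene, rose by 2.32 (SE 0.22). Of 26 calcium handling and excitation genes, 14 fell and 3 rose (14 and 3 adjusted over the list alone, camera adjusted p = 0.00312, adjusted p = 0.376 with an estimated correlation), among them atp2a2a, the calcium pump of the sarcoplasmic reticulum (-1.68, SE 0.23). Glycolysis genes split, with 22 of 39 lower and 5 higher (23 and 6 adjusted over the list alone, camera adjusted p = 0.00365, adjusted p = 0.461 with an estimated correlation). Within them gapdh fell by 2.94 (SE 0.32) and eno1b rose by 2.49 (SE 0.35).

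By camera at the preset correlation, stress and signalling lists were higher on balance and ribosomal protein genes lower. Of 38 immediate early and AP-1 genes 16 rose and 1 fell (13 and 1 adjusted over the list alone, camera adjusted p = 0.00504, adjusted p = 0.582 with an estimated correlation). Of 44 heat shock and unfolded protein response genes 27 rose and 3 fell (27 and 3 adjusted over the list alone, camera adjusted p = 0.000133, adjusted p = 0.346 with an estimated correlation). Of 16 YAP target genes 9 rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 0.0141, adjusted p = 0.339 with an estimated correlation), with ctgfa at 1.90 (SE 0.32). Of 35 apoptosis genes 14 rose and 6 fell (14 and 6 adjusted over the list alone, camera adjusted p = 0.0141, adjusted p = 0.339 with an estimated correlation). Regeneration and growth factor signals held 17 higher and 6 lower of 38 (18 and 6 adjusted over the list alone, camera adjusted p = 0.045, adjusted p = 0.339 with an estimated correlation). In this list nrg1, a cardiomyocyte mitogen, rose by 2.91 (SE 0.49) and vegfab fell by 1.65 (SE 0.27). Of 79 ribosomal protein genes 27 fell and 2 rose (18 and 2 adjusted over the list alone, camera adjusted p = 0.045, adjusted p = 0.798 with an estimated correlation). With RLE size factors in place of TMM, camera no longer passed the growth factor list (adjusted p = 0.0584) or the ribosomal list (adjusted p = 0.0782). Their medians were then 0.81 and -0.15, against 0.74 and -0.22 with TMM.

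Targets of p53 moved in both directions with injury. Of 32 tested, 11 rose and 11 fell (12 and 12 adjusted over the list alone, camera adjusted p = 0.861). Among the 6 most abundant, plk2b, sesn1, sesn3 and perp fell (log2 -1.37, -1.90, -0.81 and -0.52), while ccng1 and btg2 stood at -0.30 and 0.22 without passing edgeR (adjusted p = 0.186 and 0.803). The cell cycle inhibitor gene cdkn1a, picked out after its values were seen, rose by 1.61 (SE 0.26, edgeR adjusted p = 0.000781). The tp53 transcript rose by 0.52 (SE 0.16, edgeR adjusted p = 0.0161), a call that ended without injured wild-type replicate 3 (0.45, adjusted p = 0.0606). Among the largest single changes, myl13, a myosin light chain gene, rose from 0.582 ± 0.727 to 21.5 ± 0.629 CPM and lmod2a, an actin filament nucleator of muscle, went from 187 ± 104 to 2.82 ± 2.47 CPM (SD, n = 3).

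The second comparison asked what injury changed in tp53 mutant ventricles. Cell division, matrix and macrophage genes rose and energy metabolism genes fell here too, with all 39 DNA replication and G1/S genes and 43 of 44 G2/M and mitosis genes higher. Macrophage genes rose in 38 of 42 cases, and oxidative phosphorylation genes fell in 76 of 83. The mitotic regulator birc5a rose by 3.28 (SE 0.49), col11a1a, a fibrillar collagen gene, by 8.99 (SE 1.64), and nrg1 by 3.88 (SE 0.51). The uninjured level of col11a1a was 0.0196 ± 0.034 CPM (SD, n = 3), so that fitted fold depends on the prior count. By edgeR 5967 genes passed, 3014 higher and 2953 lower.

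In mutants the median log2 fold change was 1.51 for DNA replication (39 higher adjusted over the list alone, camera adjusted p = 1.75e-13, adjusted p = 0.416 with an estimated correlation). It was 2.30 for G2/M genes (43 adjusted over the list alone, camera adjusted p = 1.68e-14, adjusted p = 0.42 with an estimated correlation). For macrophage genes it was 2.45 (38 adjusted over the list alone, camera adjusted p = 1.14e-09, adjusted p = 0.42 with an estimated correlation), and for oxidative phosphorylation -1.07 (76 lower adjusted over the list alone, camera adjusted p = 4.4e-19, adjusted p = 0.42 with an estimated correlation). Of 45 matrix genes 37 rose and 1 fell (38 and 1 adjusted over the list alone, camera adjusted p = 2.97e-12, adjusted p = 0.381 with an estimated correlation). Fatty acid oxidation genes fell in 38 of 47 cases (38 adjusted over the list alone, camera adjusted p = 3.75e-13, adjusted p = 0.416 with an estimated correlation). Sarcomere genes fell in 17 of 28 cases (18 adjusted over the list alone, camera adjusted p = 7.97e-06, adjusted p = 0.42 with an estimated correlation).

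Erythrocyte genes fell in 11 of 23 cases in mutants and rose in 2 (11 and 2 adjusted over the list alone, camera adjusted p = 0.0213, adjusted p = 0.599 with an estimated correlation). With injury in wild type 3 fell and 3 rose, with a median of 0.29 (2 and 2 adjusted over the list alone, camera adjusted p = 0.338). The hemoglobin gene ba1l fell by 1.68 (SE 0.32) and gata1a, the erythroid transcription factor, by 1.45 (SE 0.21). Hemoglobin genes are near-identical copies, so their counts are uncertain. Of 79 ribosomal protein genes 63 fell (64 adjusted over the list alone, camera adjusted p = 1.41e-07, adjusted p = 0.537 with an estimated correlation), with a median of -0.42. Endothelial and endocardial genes fell in 19 of 35 cases and rose in 2 (19 and 2 adjusted over the list alone, camera adjusted p = 0.00201, adjusted p = 0.371 with an estimated correlation), with the receptor gene tek at -1.66 (SE 0.28). With injury in wild type 16 endothelial genes fell and 5 rose (16 and 5 adjusted over the list alone, camera adjusted p = 0.0585). Camera also passed the calcium handling, growth factor, lymphocyte, glycolysis, cytokine, immediate early, heat shock and YAP lists, 18 in all. None of the 31 lists passed with an estimated correlation in either injury comparison.

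Across the 11344 genes, injury responses in mutants and wild type correlated with Pearson's r of 0.89 and Spearman's rho of 0.90. This describes genes, which are not independent replicates, and the comparisons share no libraries. Both passed 2429 genes as higher, against 776 for independent lists, and 2571 as lower, against 872. Only 6 genes passed in opposite directions.

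**Figure D3:**
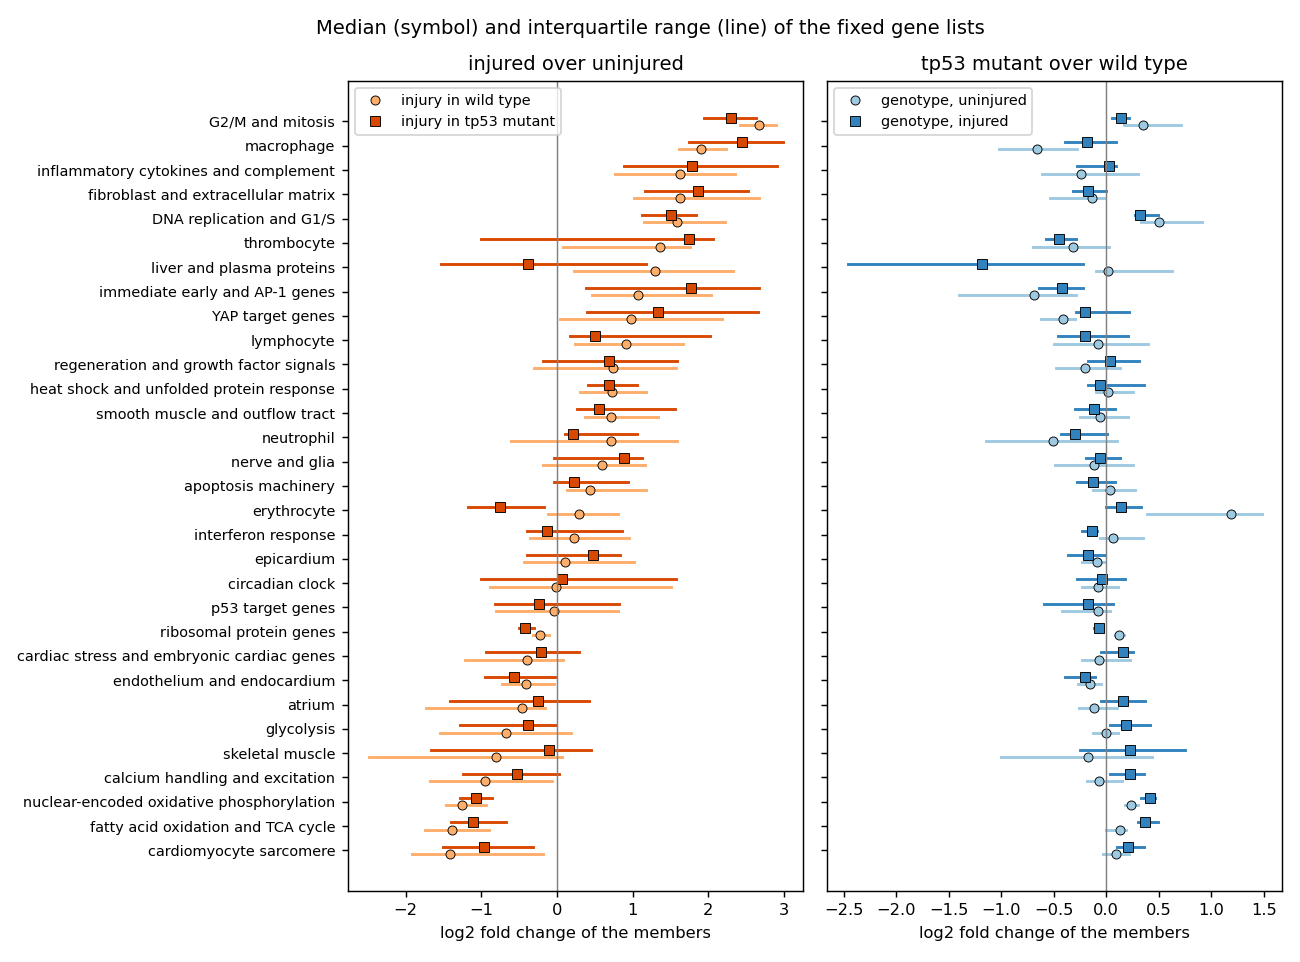
Median log2 fold change (symbols) and interquartile range (lines) of the tested members of the 31 gene lists, for injury in each genotype (left) and for mutant over wild type in each injury state (right). With injury the G2/M and mitosis median was 2.67 in wild type and 2.30 in mutants, and the erythrocyte median between genotypes was 1.19 in uninjured ventricles.

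The third comparison asked how the mutation changed uninjured ventricles. The transcript of bmb, brambleberry, known for its part in joining nuclear envelopes in early embryos, was nearly absent from mutants. It averaged 0.0829 ± 0.0721 CPM in mutants and 12.6 ± 5.03 in wild type (SD, n = 3), or 4 counts against 599. The wild-type level was 150 times higher (95% exact binomial interval 58.2 to 552, counting error only). It was the single gene past edgeR's threshold (log2 fold change -7.12, SE 0.54, adjusted p = 0.000532). With no adjustment 637 of 11344 genes had p under 0.05 by edgeR, slightly above the 0.05 share that chance alone would give. DESeq2 passed 41 genes.

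Erythrocyte genes were on balance higher in uninjured mutants, with 22 of 23 above 0 and a median of 1.19. No member passed edgeR over all genes, while 13 passed adjusted over the list alone. DESeq2 passed 8 over all genes, all higher, gata1a (1.23, adjusted p = 0.000168) and ba1l (1.49, adjusted p = 0.00355) among them. The list passed camera (adjusted p = 4.17e-33, adjusted p = 0.175 with an estimated correlation). The gata1a level was 22.6 ± 5.12 CPM in mutants against 9.74 ± 2.07 in wild type, and ba1l was 201 ± 41.4 against 72.6 ± 25.4 (SD, n = 3). DNA replication genes stood at a median of 0.50 and G2/M genes at 0.35, with 37 of 39 and 34 of 44 positive. None passed edgeR over all genes or adjusted over the list alone (camera adjusted p = 5.3e-21 and 1.37e-09, adjusted p = 0.533 and 0.81 with an estimated correlation). Immediate early genes had a median of -0.69 with 33 of 38 negative, none past edgeR's threshold over all genes or adjusted over the list alone (camera adjusted p = 4.97e-10, adjusted p = 0.575 with an estimated correlation).

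Macrophage genes had a median of -0.66, none past edgeR's threshold over all genes or adjusted over the list alone (camera adjusted p = 0.0185, adjusted p = 0.943 with an estimated correlation). Without uninjured wild-type replicate 2 that median was 0.50, and camera passed the list as higher (adjusted p = 0.000148). Of the 11 lists that camera passed in uninjured ventricles, only 5 passed in the same direction without that library. This library held slc7a7, an amino acid transporter gene of macrophages, at 71.1 CPM against 3.04 and 2.79 in the other wild-type libraries. Camera passed 6 further lists with no member past edgeR's threshold over all genes: neutrophil, YAP targets, sarcomere, oxidative phosphorylation, fatty acid oxidation and ribosomal protein genes. In the sarcomere list acta1a passed by DESeq2 (1.2, adjusted p = 0.000185) and, without uninjured wild-type replicate 2, by edgeR (1.46, adjusted p = 0.0271). All 6 lists were lost with an estimated correlation (adjusted p from 0.374 to 0.943). Targets of p53 had a median of -0.08, with 0 past edgeR's threshold over all genes, 1 lower adjusted over the list alone and camera adjusted p = 0.128. In a fit of these 6 libraries alone, edgeR no longer passed bmb (log2 -7.08, adjusted p = 0.0918), and without uninjured wild-type replicate 2 it passed 10 genes.

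The fourth comparison asked how the mutation changed injured ventricles. Transcripts of mdm2 and bmb were lower in mutants, and both passed edgeR. The mdm2 log2 fold change was -2.35 (SE 0.12, adjusted p = 1.08e-05), with every mutant library at or below 18.6 CPM and every wild-type library at or above 82.3. For bmb it was -4.85 (SE 0.38, adjusted p = 0.000326), at 71 counts in mutants against 2073, with wild type 28.8 times higher (95% exact binomial interval 22.7 to 37, counting error only). With no adjustment 915 genes had p under 0.05 by edgeR, and DESeq2 passed 81 genes.

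Targets of p53 were lower on balance in injured mutants. Of 32 tested, 23 were negative, 1 fell past edgeR's threshold over all genes, and 6 fell and 1 rose adjusted over the list alone. The list passed camera with the preset (adjusted p = 9.9e-08) and with the estimated correlation (adjusted p = 0.00584), and fry (adjusted p = 0.00412). Below the edgeR threshold over all genes stood tp53inp1, a p53-induced nuclear protein gene (-1.32, SE 0.26, adjusted p = 0.296), and casp8, an apoptosis initiator (-0.64, SE 0.15, adjusted p = 0.296). DESeq2 passed both, at -1.35 (adjusted p = 0.00142) and -0.68 (adjusted p = 0.0243). The pro-apoptotic gene bbc3 stood at -1.31 (SE 0.37, edgeR adjusted p = 0.302). Against the direction of the list, tigarb was at 0.66 (SE 0.16, edgeR adjusted p = 0.296). The values for cdkn1a were -0.34 (SE 0.25, edgeR adjusted p = 0.818), so no difference was detectable in it.

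Most energy metabolism genes stood slightly higher in injured mutants, but as groups they passed only camera with the preset correlation (fry adjusted p = 0.479 for each of the next 2 lists). Of 83 oxidative phosphorylation genes 82 were positive, with a median of 0.42, and of 47 fatty acid oxidation and TCA cycle genes 43 were positive, with a median of 0.37. None passed edgeR over all genes or adjusted over the list alone (camera adjusted p = 6.73e-21 and 6.28e-11, adjusted p = 0.595 for each with an estimated correlation). In the second list acsl1a passed by DESeq2 (0.88, adjusted p = 0.0496) and, without injured mutant replicate 2, by edgeR (1.19, adjusted p = 0.013). DNA replication genes had a median of 0.32 with 38 of 39 positive and none past edgeR's threshold over all genes or adjusted over the list alone (camera adjusted p = 1.21e-06, adjusted p = 0.711 with an estimated correlation). G2/M genes had a median of 0.14 (camera adjusted p = 0.456), with none past edgeR's threshold over all genes or adjusted over the list alone. Sarcomere genes stood at 0.21 (camera adjusted p = 0.0169, adjusted p = 0.78 with an estimated correlation), with none past edgeR's threshold over all genes or adjusted over the list alone and 1 higher by DESeq2.

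Endothelial genes were negative in 30 of 35 cases, with a median of -0.20 and none past edgeR's threshold over all genes or adjusted over the list alone (camera adjusted p = 8.82e-07, adjusted p = 0.104 with an estimated correlation). The endothelial factor genes fli1a and etv2 stood at -0.55 (SE 0.16) and -0.45 (SE 0.12). Liver and plasma protein genes had a median of -1.18 (camera adjusted p = 0.0169, adjusted p = 0.595 with an estimated correlation), with none past edgeR's threshold over all genes or adjusted over the list alone. Immediate early genes had a median of -0.42 (camera adjusted p = 0.000228, adjusted p = 0.711 with an estimated correlation), again with none past either threshold. Without injured wild-type replicate 1 these medians were 0.09 and 0.14. That library held the yolk precursor gene vtg1 at 40.8 CPM against 0 and 0.124 in the other injured wild-type libraries. Camera also passed the thrombocyte, ribosomal protein, glycolysis, apoptosis, calcium handling and skeletal muscle lists, which were lost with an estimated correlation (adjusted p from 0.498 to 0.82).

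The fifth comparison averaged the genotype difference over both injury states. Only bmb (log2 fold change -5.98, SE 0.33, adjusted p = 1.56e-05) and mdm2 (-1.44, SE 0.09, adjusted p = 1.79e-05) passed edgeR, both lower in mutants. DESeq2 passed 134 genes, and edgeR passed 35 without uninjured wild-type replicate 2. Targets of p53 were negative in 24 of 32 cases, with 1 lower by edgeR over all genes and 5 lower and 1 higher adjusted over the list alone. They again passed camera with the preset (adjusted p = 4.35e-06) and the estimated correlation (adjusted p = 0.0173). Among the 6 most abundant targets, plk2b, a polo-like kinase gene, came nearest to the threshold (-0.47, SE 0.12, edgeR adjusted p = 0.248). DESeq2 passed 5 targets, all lower, with plk2b (adjusted p = 0.0271), bbc3 (adjusted p = 0.00478) and tp53inp1 (adjusted p = 0.000452) among them. Without uninjured wild-type replicate 2, edgeR passed bbc3 (adjusted p = 0.0185) and tp53inp1 (adjusted p = 0.0477).

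Several genes just outside the threshold in this averaged contrast were picked out after their values were seen. The heart transcription factor gene tbx5b, itself a neighbour of tp53, stood at -1.36 (edgeR adjusted p = 0.06), cyp24a1, the vitamin D-degrading enzyme gene, at -2.40 (adjusted p = 0.06) and lnx1, a ubiquitin ligase gene, at -2.48 (adjusted p = 0.06). Without uninjured wild-type replicate 2 they passed, at -1.46 (adjusted p = 0.0185), -2.06 (0.0374) and -2.33 (0.0442). Neighbours of tp53 in the GRCz12tu gene table were tested as a group, with edgeR's calls in the averaged contrast as the planned measure. Of 251 tested genes within 10 Mb, 0 passed edgeR in the averaged contrast, against 2 of 11006 others. With 2 calls in all, this Fisher exact test could not show an enrichment. The alternatives to this planned test were chosen after the values were seen. DESeq2 passed 14 of 265 neighbours against 119 of 11720 others (odds ratio 5.44, Fisher exact p = 1.39e-06). Without uninjured wild-type replicate 2, edgeR passed 6 of 254 against 29 of 11205 (odds ratio 9.32, Fisher exact p = 0.000106). That library held the neighbours ccdc125 and fam219ab near mutant levels (0.803 and 0.309 CPM), so leaving it out favours a genotype difference in neighbours. Genes are not independent replicates, so these Fisher p-values do not measure the spread between samples.

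**Figure D4:**
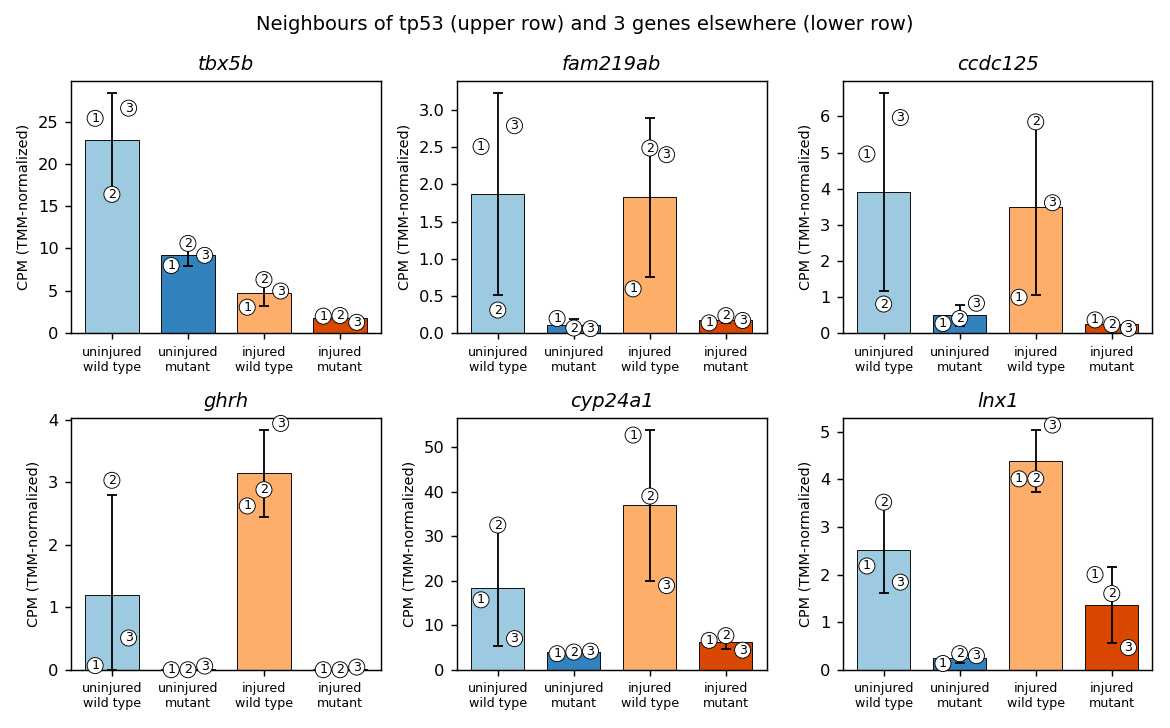
TMM-normalized CPM of 3 neighbours of tp53 (upper row) and 3 genes elsewhere (lower row), by group, with means (bars), SD (error bars, n = 3) and single libraries (numbered circles). Injured wild-type replicate 1 and uninjured wild-type replicate 2 held ccdc125 at 0.991 and 0.803 CPM.

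The last comparison asked whether the injury response differed between genotypes. It did for mdm2, whose interaction was -1.81 on the log2 scale (SE 0.17, edgeR adjusted p = 0.00413). Its mean rose from 57 to 92.3 CPM with injury in wild type and stood at 39.2 and 18.1 CPM in uninjured and injured mutants. No other gene passed edgeR, while DESeq2 passed 15. An unadjusted p under 0.05 was found by edgeR for 442 of 11344 genes, fewer than the 0.05 share that chance alone would give. The next smallest adjusted p was that of cplx2l (2.36, SE 0.36, edgeR adjusted p = 0.227), followed by gata1a (-1.57, SE 0.29, adjusted p = 0.493).

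Among the lists, erythrocyte genes had the smallest camera p for the interaction, with a median of -0.87 and no member past edgeR's threshold over all genes (7 lower adjusted over the list alone). DESeq2 passed 2 of them over all genes, gata1a (-1.62, adjusted p = 0.00125) and nfe2 (-1.53, adjusted p = 0.039). Camera passed the list (adjusted p = 2.62e-18, adjusted p = 0.241 with an estimated correlation). Between genotypes the erythrocyte median was 1.19 in uninjured but 0.14 in injured ventricles, where camera did not pass the list (adjusted p = 0.483). The interaction of this list thus rests on the difference between uninjured groups. G2/M genes had a median of -0.29 and DNA replication genes of -0.19, with none past edgeR's threshold over all genes or adjusted over the list alone (camera adjusted p = 0.000129 and 0.00234, adjusted p = 0.81 for each with an estimated correlation). The p53 target list had a median of -0.04, with mdm2 as the 1 member past edgeR's threshold over all genes and 2 lower adjusted over the list alone (camera adjusted p = 0.00234, adjusted p = 0.147 with an estimated correlation). Camera passed 12 lists in this contrast, and none passed with an estimated correlation or by fry.

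The remaining lists described other tissues and cell types and did not pass camera in any contrast. Medians with injury in wild type and in mutants were 0.11 and 0.47 for epicardium, 0.72 and 0.55 for smooth muscle and outflow tract, -0.46 and -0.25 for atrium, and 0.59 and 0.88 for nerve and glia. They were -0.40 and -0.21 for cardiac stress and embryonic genes and -0.01 and 0.06 for circadian clock genes.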

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

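The tests of the neighbours of tp53 in this part, the second test of a cardiomyocyte share and the mitochondrial ribosomal gene set were chosen only after the result was seen. The other explanations weighed here were tested as planned.

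The injury response differed between genotypes for mdm2 (interaction -1.81, edgeR adjusted p = 0.00413). Camera also passed 12 lists at the preset correlation, and 0 of them passed with the estimated correlation or by fry. They are given as median interaction with camera's adjusted p at the preset correlation and then with the estimated one. Erythrocyte genes had -0.87 (2.62e-18 and 0.241), ribosomal protein genes -0.19 (8.52e-14 and 0.638) and G2/M and mitosis genes -0.29 (0.000129 and 0.81). Fatty acid oxidation and TCA cycle genes had 0.30 (0.0014 and 0.81) and DNA replication genes -0.19 (0.00234 and 0.81). The p53 target genes had -0.04, with 16 positive and 16 negative members and a downward test (0.00234 and 0.147). Apoptosis genes had -0.18 (0.00315 and 0.219), liver and plasma protein genes -1.50 (0.00489 and 0.433), and endothelial genes -0.09 (0.013 and 0.433). Thrombocyte genes had 0.03 with a mean of -0.15 and a downward test (0.022 and 0.638), interferon genes -0.17 (0.0228 and 0.639) and oxidative phosphorylation genes 0.17 (0.0415 and 0.877). The last call was lost, with the test pointing downward, without injured mutant replicate 1, injured wild-type replicate 1 or uninjured mutant replicate 3 (adjusted p = 0.466, 0.453 and 0.979), and it was lost in the same direction without injured mutant replicate 3 or uninjured wild-type replicate 1 or 2.

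For the interaction, 8 of 100 splits of the libraries within each injury state gave at least 1 gene, the highest other split giving 16, so this count cannot exclude chance for the number of genes. It is not a clean test, since 6 of the 8, the real one included, kept the injured genotypes as they were and so held the real difference. Of the 91 splits that broke them up, 2 gave at least 1 gene. For the averaged genotype contrast, 3 of 100 splits, the real one included, gave at least 2 genes, and 2 of the 3 kept the injured genotypes. The 100 were drawn from 200 possible splits. A share of 3 in 100 lies under the planned 0.05, which argues against chance. Another split gave 16 genes, more than the real one, so this evidence is weak. Comparisons of 3 against 3 have 10 splits, too few for a share under 0.05. Injury gave 6269 genes in wild type and 5967 in mutants, and 0 in any other split. The genotype contrast gave 2 genes in injured ventricles, with 0 in any other split. In uninjured ventricles it gave 1 gene and another split gave 116, and 3 of 10 splits reached 1. The split with 116 genes set uninjured mutant replicates 1 and 3 with uninjured wild-type replicate 2 against the rest, which points to a structure of the samples other than genotype.

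The first pattern weighed is uninjured wild-type replicate 2, which lay nearer the injured libraries than any other uninjured library. A swapped label with an injured library is argued against, since over 655 genes that change at least 4-fold with injury in mutants the median share of the injured profile in it was 20.8% (interquartile range 11 to 39.6). RNA or tissue from injured ventricles could be mixed in. The median share was 17.9% over 500 rising genes and 36.9% over 155 falling genes (interquartile range 17.3 to 59.4), which neither meets nor excludes a single share. A difference between the fish of that sample stays open and was not tested.

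The second pattern is a set of genes near tp53 that were lower in mutants. Of 251 tested neighbours within 10 Mb, 25 were lower at an unadjusted p under 0.05, against 441 of 11006 others (Fisher exact odds ratio 2.65, 95% interval 1.66 to 4.07, p = 6.48e-05), and 26 were higher, against 644 (odds ratio 1.86, 1.18 to 2.82), so the excess was not of lower genes alone. In either direction the odds ratio was 2.33, against 1 for injury in wild type. It was 2.04 over the whole chromosome of tp53, a set that includes these neighbours (17.8% of 708 genes, against 9.6% of 10549). The excess was thus not shown to be particular to genes within 10 Mb. These tests count genes, which are not independent replicates, so their p-values and intervals do not measure the spread between samples. Injured wild-type replicate 1 and uninjured wild-type replicate 2 held ccdc125 and fam219ab near mutant levels. Their mdm2 was 4.43 and 1.56 times that of the highest mutant library of the same injury state. Against the highest mutant library of either state it was 2.01 and 1.56 times. Low levels of both genes thus occurred without mutant-level mdm2. Since mdm2 separated the genotypes in all libraries, any wild-type library would pass this comparison. It therefore cannot exclude lower p53 activity as a cause in mutants. Sequence variants linked to the mutant allele may account for these genes, a hypothesis found and tested on the same data.

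The third pattern is that all 68 mitochondrial ribosomal protein genes were higher in injured mutants than in injured wild type, with a median of 0.46 (interquartile range 0.39 to 0.56), 0 past edgeR's threshold and 14 past that of DESeq2. Library scaling is argued against, since the lowest median under the other scalings was 0.42. A larger cardiomyocyte share was undecided in the planned test: the genes fell with injury in wild type (median -0.57), as a cell share would need, while sarcomere genes rose less than they did in injured mutants (0.21, interquartile range 0.10 to 0.36). A second test set the same genes side by side per library after the result was seen, so it is not separate evidence. The mean of these genes minus that of sarcomere genes was 0.28 higher in injured mutants. This lay beyond the pooled SD of 0.15 that its rule first named, and so against such a share by that rule. The rule was replaced, after the value was known, by complete separation of the libraries, and was then restored. Separation was not met, with the lowest injured mutant at -4.29 and the highest injured wild type at -4.26 (exact permutation p = 0.2, two-sided, smallest possible 0.1). The second test therefore cannot decide. A cardiomyocyte share as the whole or a partial cause stays open, as does sarcomere RNA lowered within cells.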

How the results depend on the processing

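The alternatives for genes near tp53 were chosen after seeing the data; the others were fixed before. The calls of mdm2 and the correlation of injury responses kept their direction and side of the threshold under every alternative run. Injury calls in wild type numbered 4653 to 6795, but which direction had more turned: 3213 higher and 3001 lower with RLE, 3367 and 3091 with DESeq2, and 3508 and 3287 without uninjured wild-type replicate 2, and likewise without any 1 uninjured mutant library. In mutants it turned with TMM without 3 lists (2969 and 3003), and without injured mutant replicate 1 or any 1 uninjured mutant library. The mdm2 interaction ranged from -1.96 to -1.74 (adjusted p at most 0.0315), and its difference in injured ventricles from -2.42 to -2.28. DESeq2 passed 41 genes for genotype in uninjured ventricles, 81 in injured, 134 averaged and 15 for the interaction, with 14 near tp53. A fit of the uninjured libraries alone passed 0. Leaving out single libraries gave 1 to 10 genes in uninjured, 2 to 4 in injured and 2 to 35 in the averaged contrast, with 0 to 6 near tp53. The highest of each came without uninjured wild-type replicate 2, and for injured ventricles also without uninjured mutant replicate 1. The cause was not tested.

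For lists, an estimated correlation left 0 of 17 for injury in wild type, 0 of 18 for injury in mutants, 0 of 11 for uninjured, 1 of 14 for injured, 1 of 11 for averaged genotype and 0 of 12 for the interaction. By fry 21 lists passed for injury in wild type (16 of the 17) and 23 in mutants (17 of the 18), while the genotype contrasts and the interaction kept 0, 1, 1 and 0. The 1 genotype list kept was that of p53 target genes. Without single libraries 9 to 18 lists passed in injured ventricles, the fewest without injured wild-type replicate 1. In uninjured ventricles 8 to 13 passed. Without uninjured wild-type replicate 2, only 5 of the 11 uninjured lists passed in the same direction. With an estimated correlation camera uses the few residual degrees of freedom of the fit, and lists with an estimate of 0.01 were lost as well, such as apoptosis and lymphocyte genes for injury in wild type.

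Reversals concerned small or single-library values. In uninjured ventricles sesn3 (-0.01) stood at 0.01 with RLE, with DESeq2 and in the fit of the compared groups. Over left-out libraries the ranges were -0.37 to 0.74 for btg2 with injury in wild type. In uninjured ventricles they were -0.16 to 0.11 for ccng1, -0.18 to 0.28 for sesn1, -0.07 to 0.10 for sesn3 and -2.86 to 0.84 for slc7a7. In injured ventricles they were -0.40 to 0.11 for sesn1, -0.01 to 0.30 for sesn3, -9.0 to 1.1 for vtg1 and -3.25 to 1.49 for vtg2. Averaged, they were -0.20 to 0.10 for sesn1 and -0.01 to 0.15 for sesn3. For the interaction they were -1.02 to 1.31 for rgs18, -0.50 to 0.01 for sesn1 and -4.25 to 0.49 for vtg2. List medians ranged from -1.08 to 0.50 (macrophage, uninjured), -0.64 to 0.11 (macrophage, averaged), -2.01 to 0.09 (liver, injured), -0.76 to 0.14 (immediate early, injured) and 0.00 to 0.32 (oxidative phosphorylation, interaction). The macrophage, slc7a7 and rgs18 values turned without uninjured wild-type replicate 2, and the vtg1, vtg2, liver and immediate early values without injured wild-type replicate 1. The oxidative phosphorylation test turned without that library, injured mutant replicate 1 or uninjured mutant replicate 3. The cause was not tested.

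With the replicate number as a block, 5827 genes passed for injury in wild type and 5484 in mutants, and 1, 2, 2 and 1 for uninjured, injured, averaged genotype and interaction. Camera then lost macrophage genes in uninjured ventricles (-0.46, adjusted p = 0.1) and oxidative phosphorylation genes for the interaction (0.17, adjusted p = 0.0629). Of 18 same-numbered pairs, 3 had a correlation of deviations over 0.1 (range -0.40 to 0.25), and 1 of 12 libraries correlated best with its own number. No pairing by number was detected, though with 3 libraries per group it cannot be excluded. With 3 libraries per group, changes of about 2-fold in the interaction are often missed.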

Other observations

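The gene sets and genes in this part were chosen only after the result was seen. Mitochondrial protein import genes (timm and tomm genes) moved with the mitochondrial ribosomal protein genes between genotypes. With injury the import genes had medians of -0.23 in wild type and 0.05 in mutants, and the ribosomal protein genes of -0.57 and -0.30. All 20 were higher in injured mutants, with a median of 0.38 (interquartile range 0.28 to 0.46), 0 past edgeR's threshold and 4 past that of DESeq2. Camera with an estimated correlation gave, among 12 tests of 2 sets in 6 contrasts, an unadjusted p of 0.0151 for this set and 0.0153 for the 68 mitochondrial ribosomal protein genes. Without injured wild-type replicate 1 the medians were 0.34 and 0.39. In uninjured ventricles both sets had a median of 0.21, with 18 of 20 and 66 of 68 genes positive and 0 past edgeR's threshold (camera with an estimated correlation, unadjusted p = 0.108 and 0.158). The interaction had medians of 0.18 and 0.28 (unadjusted p = 0.252 and 0.199), so a difference between injury states was not shown.

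The growth hormone-releasing hormone gene ghrh was nearly absent from mutants, with 1 count over the 3 injured mutant libraries against 227 in injured wild type (ratio 224, 95% exact binomial interval 39.8 to 8.88e+03, counting error only). It missed edgeR's threshold in the averaged contrast (log2 fold change -6.37, adjusted p = 0.06). Without uninjured wild-type replicate 2 it passed there (-5.37, adjusted p = 0.0235) and in injured ventricles (-7.32, adjusted p = 0.00983). In uninjured wild type it was uneven, at 0.0661, 3.03 and 0.508 CPM in replicates 1, 2 and 3.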
